A study of Escherichia coli str. K-12 substr. MG1655 with 12 samples.

How the data were processed

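Contact maps of Escherichia coli MG1655 were analysed for 12 samples in 4 groups of 3, exponential and stationary phase with and without formaldehyde. Per the labels' protocols, cells were fixed, lysed and digested with the restriction enzyme MluI, and DNA was sheared before Illumina library preparation. Replicate 3 of each group had no biotin labelling or enrichment, per the labels. The aligner, the filters, the normalisation method and the genome build are not given in the sources used here.

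The authors deposited 4 maps whose values are a normalised contact signal, 1 per group, so the samples had been pooled. The deposited exponential maps have 464 bins of nominally 10 kb and the stationary maps 233 bins of nominally 20 kb. In 3 maps every row, diagonal included, sums to the number of bins, which shows that the deposited signal was balanced. In the exponential map labelled uncrosslinked, 4156 cells near the diagonal hold the constant 1 and row sums vary from 23.1 to 31.5. The authors also deposited 2 tables of log10 ratios. The stationary log10 table equals crosslinked over uncrosslinked to a tolerance of 1e-12, with 318 empty cells where the uncrosslinked value is 0. The exponential deposited log10 table follows the reverse order of the labelled maps. Counts could not be recovered from the balanced values, so depth is unknown and no counting interval is given.

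The exponential maps were summed to 20 kb, and all maps were trimmed to 232 common bins. Far coverage was the sum of contacts spanning at least 100 kb. The design fixed before the data were examined had named all off-diagonal contacts. This was changed because balancing fixes the row totals and the near-diagonal cells of 1 map are constant, so that all off-diagonal contacts became an alternative for the other maps. Bins in the lowest 5% of far coverage of a map were left out. The coverage ratio used medians within 200 kb of oriC and dif, with 2000 bootstrap draws over bins and rotations of both windows. Coverage changes between maps were log2 ratios after removal of a running median over 400 kb, and the threshold was 1 log2 unit. The slope was a least squares fit over 12 log-spaced distance classes up to 1000 kb, starting at 60 kb because cells up to 2 bins from the diagonal were left out.

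For patterns, each map was balanced over pairs at least 60 kb apart and divided by the mean at each circular distance. Correlations used log2 of this value plus 0.1 across pairs of bins. Gene lists were compared with 10000 random lists of as many bins, over pairs at least 100 kb apart. Macrodomain borders were rounded to 0.1 Mb. All resampling used seed 1. These percentiles describe single maps, and no test across samples was made.

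Gene names and nominal bins came from the RefSeq annotation of assembly ASM584v2, which may not be the authors' build. No coordinates are printed from it, and 38 of 180 list genes lie within 2 kb of a bin border. Named bins were chosen by a rule fixed before the data were examined: the 5 highest and 5 lowest log2 coverage ratios in each comparison, the top 5 pairs at least 500 kb apart in each map, the landmarks oriC and terminus, and members of 11 fixed lists. The repeat families (Rhs elements, rRNA operons, lambdoid and CP4 prophages) were drawn up afterwards.

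The coverage ratio, distance slope, macrodomain enrichment, list clustering, list coverage change and map correlation were tested on simulated maps of 232 bins. The other statistics were not simulated. The simulated exponential maps had the spread of the real maps, except for the list coverage change. In that test, and in the simulated stationary maps that held no effect, the spread was smaller than in the real maps. Over 20 simulations, a built-in origin over terminus ratio of 1.36 was recovered as 1.34 ± 0.0120 (SD), a list enrichment of 1.45 as 1.43 ± 0.0586 and a map correlation of 0.5 as 0.491 ± 0.0048. The simulated maps had no dominant diagonal, were not balanced to equal row sums and held no pairs of repeated loci. Recovery was therefore shown for unbalanced maps only. Alternatives varied the bins left out, window, trend, distance range, normalisation, scale, bin size, repeats and gene placement. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.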

Results

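Chromosome contacts were measured by Hi-C in Escherichia coli K-12 MG1655, the standard laboratory strain, grown in minimal medium with glycerol. Hi-C joins DNA ends that lie close together in the cell, and sequencing of the junctions counts how often each pair of chromosomal positions is joined. The 12 samples fell into 4 groups of 3, exponential or stationary phase, each with 1% formaldehyde for 20 min or with buffer alone. The deposited data hold 1 pooled contact map per group. No spread between replicates could be computed, no test across samples was possible, and the read depth behind the maps is unknown. Errors below are spreads over bins, distance classes or resampled stretches of a single map, and percentiles describe that map alone. In 4 samples, replicate 3 of each group, the biotin enrichment of junctions was omitted, and their part in each pooled map is unknown. Positions are nominal bins of 20 kb counted from 1, named by the genes that the annotation places in them.

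The labels of the exponential maps need a caution. The deposited stationary ratio table equals log10 of crosslinked over uncrosslinked, whereas the deposited exponential table followed the opposite order of the maps as labelled (r = -0.933 in the stationary order across 26332 pairs of bins, which are not independent). The names of these maps or the order of that ratio must therefore differ between growth phases. The exponential maps are called "labelled crosslinked" and "labelled uncrosslinked" throughout, and each direction drawn between them depends on those labels.

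The first comparison asked how growth phase changed contacts along the chromosome. In exponential phase, far coverage (contacts at least 100 kb apart) was highest around the replication origin oriC, beside mnmG and close to the initiator gene dnaA, and lowest around the terminus, where hipA lies beside the dif resolution site. Median far coverage within 200 kb of oriC was 1.39 times that within 200 kb of dif in the labelled crosslinked map (95% bootstrap interval 1.35 to 1.42) and 1.34 times in the labelled uncrosslinked map (1.30 to 1.36). In stationary phase the ratio was 0.996 (0.976 to 1.01) with formaldehyde and 1.05 (0.980 to 1.09) without. As deposited, row totals were equal in all maps except that labelled exponential uncrosslinked. So 1.39, 0.996 and 1.05 compare the share of each bin's contacts that were far, while 1.34 compares values as deposited. Both exponential intervals lay above both stationary intervals, so this difference did not depend on which exponential map was which. The smoothed maximum lay in bin 196 and in bin 194 of the exponential maps, against bin 197 for oriC. The minima lay in bins 74 and 79, against bin 80 for dif.

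Both arms of the chromosome contributed. In the labelled crosslinked exponential map, far coverage changed by -0.21 ± 0.01 log2 units per Mb (SE over resampled stretches) on the clockwise arm and by -0.22 ± 0.01 on the counterclockwise arm. The labelled uncrosslinked map gave -0.19 ± 0.01 and -0.20 ± 0.01. When both windows were rotated together around the chromosome, 1 of 232 placements reached the observed ratio in the labelled crosslinked map, the real one, and 6 of 232 in the labelled uncrosslinked map. Leaving out the 5% of bins with the lowest coverage removed terminus bins in particular, with 12 and 10 kept of the 21 bins around dif.

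**Figure D1:**
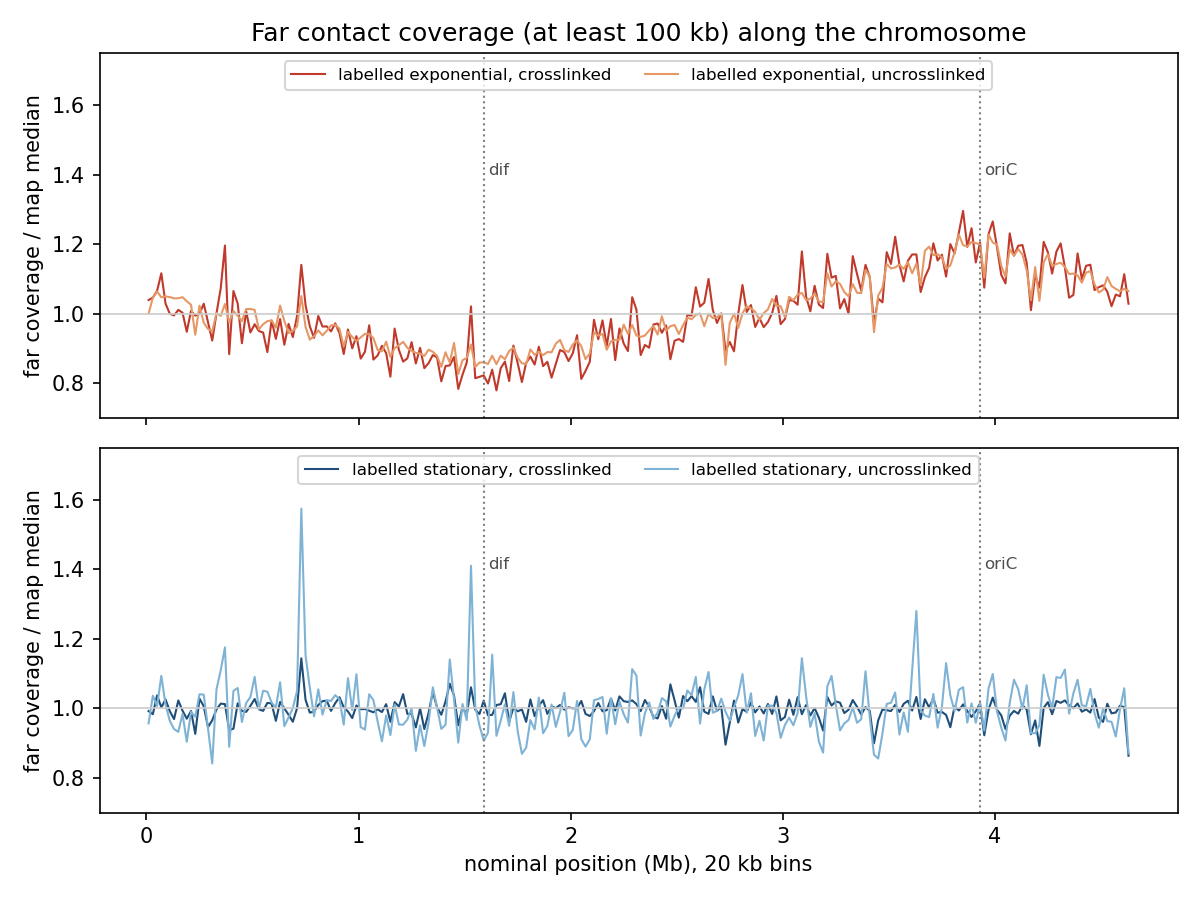
Far contact coverage of each 20 kb bin divided by the map median (y axis) against nominal position in Mb (x axis), for the exponential maps (top) and the stationary maps (bottom); dotted lines mark dif and oriC. The exponential maps fall from oriC to dif with ratios of 1.39 and 1.34, while the stationary ratios are 0.996 and 1.05 and single bins with rhsC and rhsE stand out without formaldehyde.

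Beyond this gradient, far coverage of single bins differed little between growth phases. After a running median over 400 kb was removed, no bin changed by more than 1 log2 unit in either direction in any of the 4 comparisons. With all contacts off the diagonal, the measure named before the data were examined, 26 bins passed that limit in exponential over stationary phase for the maps labelled crosslinked, and 1 bin did for formaldehyde in stationary phase. In the maps labelled crosslinked, the bins highest in exponential over stationary phase held the lac operon of lactose use (bin 19, log2 ratio 0.25), tktA and metK, for transketolase and S-adenosylmethionine synthase (bin 155, 0.23), the iron-sulfur cluster genes iscA, hscA and fdx (bin 133, 0.19), rhsE (bin 77, 0.19), and the cytochrome c maturation genes ccmA to ccmH (bin 115, 0.17). The lowest held prophage genes: intS (bin 124, -0.24), yfjJ to psaA (bin 139, -0.18), intD (bin 29, -0.14) and racR (bin 72, -0.13), followed by the acid response gene cadB (bin 218, -0.13). The SD over the 208 bins was 0.07. The highest bins went the other way in the maps labelled uncrosslinked, before trend removal. Bins 19, 155, 133, 77 and 115 had far coverage of 1.03, 1.06, 1.00, 0.911 and 0.967 times the exponential map's median. The stationary uncrosslinked values were 1.18, 1.14, 1.10, 1.41 and 1.11. Bins 19, 77, 155 and 115 were also among the highest of labelled crosslinked over labelled uncrosslinked exponential maps. These ratios were thus not shared by both growth phase comparisons.

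In the maps labelled uncrosslinked, the lowest ratios of exponential over stationary phase belonged to bins with rhsC (bin 37, log2 ratio -0.50), rhsE (bin 77, -0.45), rhsB (bin 182, -0.35), dcp with Qin prophage genes (bin 82, -0.25) and rhsA (bin 189, -0.22). The rhs genes are long, closely similar copies encoding large Rhs proteins. The highest ratios belonged to bins with rpsB and bamA (bin 10, 0.16), malT and malP of maltose use (bin 178, 0.13), the RNA polymerase genes rpoB and rpoC (bin 210, 0.13), the hyf operon (bin 131, 0.13) and the liv and ugp transport genes (bin 180, 0.13). The SD over 211 bins was 0.09. The stationary uncrosslinked map was itself high in bins 37, 77, 182 and 82, at 1.57, 1.41, 1.28 and 1.15 times its median. Stationary crosslinked cells had 1.14, 1.06, 1.03 and 0.981. These bins were also the lowest with formaldehyde relative to without in stationary phase. Bins 210, 131 and 180 were likewise among the highest in that comparison. Both sets thus share the stationary uncrosslinked map and cannot be assigned to growth phase alone.

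Beyond 60 kb, contact frequency changed little with distance in any map; in 3 maps values fell steeply at shorter distances. From 60 to 1000 kb, the slope of log10 contact value against log10 distance was -0.0502 ± 0.0045 (SE over 12 distance classes) in stationary cells with formaldehyde and -0.0222 ± 0.0102 without. It was -0.00864 ± 0.0044 and -0.00742 ± 0.0032 in the exponential maps labelled crosslinked and uncrosslinked. The labelled crosslinked exponential slope was shallower than the stationary crosslinked slope by 0.0416 ± 0.0062, a difference with no test across samples. Pairs 60 to 200 kb apart exceeded pairs at least 2000 kb apart by a factor of 1.11 in stationary crosslinked cells and by 1.03 to 1.07 in the other maps.

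**Figure D2:**
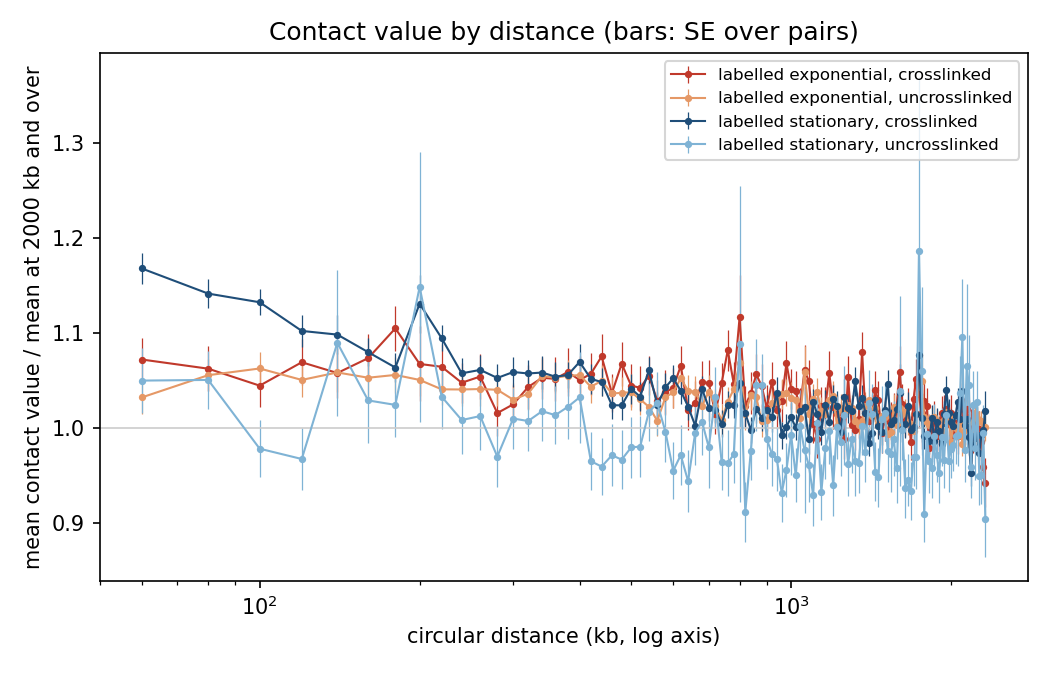
Mean contact value at each circular distance divided by the mean at 2000 kb and over (y axis) against distance in kb on a log axis (x axis), for the 4 maps; bars are the SE over pairs of bins. The stationary crosslinked map starts highest and has the steepest slope, -0.0502, while the exponential maps are close to flat.

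In 3 of the 4 maps most contact value lay near the diagonal. Contacts spanning under 100 kb made up 84.6% of off-diagonal value in the labelled crosslinked exponential map, 80.1% in stationary crosslinked cells and 95.4% in stationary uncrosslinked cells, with SDs over 220 bins of 14.7, 14.7 and 9.16 percentage points. The share was not computed for the labelled uncrosslinked exponential map, whose 4156 cells up to 4 bins of 10 kb from the diagonal all hold the value 1. As deposited, far contacts made up 65.4% of all value in that map, the diagonal included, against 1.95%, 2.74% and 0.537% in the other 3.

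The second comparison asked what formaldehyde changed. In stationary phase, far contacts were more frequent with formaldehyde in all 232 bins, by a median factor of 5.14 (SD over bins 0.325). In exponential phase as labelled, the factor was 0.509 (SD 0.0229), below 1 in all 232 bins. Both stationary maps were balanced to the same row totals, so 5.14 compares the share of contacts that were far and not their absolute number. Row totals of the map labelled exponential uncrosslinked vary as deposited, so 0.509 is a ratio of values as deposited. In the authors' deposited exponential ratio table, the median log10 ratio was -0.00936 on the diagonal and 0.296 over far pairs. The far value matched the maps, at 0.296 for labelled uncrosslinked over labelled crosslinked. The diagonal value could not come from a map whose diagonal holds 1, so the values behind the table lacked those constants. The constants may thus have been put in after balancing, which would make 0.509 a ratio of shares. This was not checked.

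In stationary phase, the bins lowest with formaldehyde relative to without held rhsE (bin 77, log2 ratio -0.43), rhsC (bin 37, -0.42), rhsB (bin 182, -0.29), dcp and Qin genes (bin 82, -0.27) and tktA (bin 155, -0.26). The highest held intS of a cryptic prophage (bin 124, 0.19), the hyf operon (bin 131, 0.18), the liv and ugp genes (bin 180, 0.15), hipA (bin 80, 0.14) and rpoB (bin 210, 0.13). In exponential phase as labelled, the lac operon (bin 19, 0.24), rhsE (bin 77, 0.19), tktA (bin 155, 0.17), the prp and cyn genes (bin 18, 0.14) and the ccm genes (bin 115, 0.13) were highest. The lowest were yfjJ to psaA (bin 139, -0.18), intS (bin 124, -0.16), the tau operon (bin 20, -0.13), intD (bin 29, -0.13) and the tdc and gar genes (bin 164, -0.11). SDs over bins were 0.09 in stationary and 0.06 in exponential phase. The rhsE, tktA and intS bins thus had opposite signs in the growth phases under the given labels.

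The contact patterns of different maps were only weakly related at 20 kb once distance and coverage were removed. Pearson's r across pairs of bins was 0.0450 between growth phases for the maps labelled crosslinked (Spearman's rho 0.0124) and 0.0484 for those labelled uncrosslinked (rho 0.0263). Between crosslinking states it was 0.0341 in exponential (rho 0.00642) and 0.0542 in stationary phase (rho 0.0224). Each r exceeded all 231 rotations of one map against the other, of which the highest was 0.0214. With 23 bins of repeated loci left out, an alternative chosen after seeing the data, the 4 values were 0.0104, 0.0115, 0.00452 and 0.0130, and 32, 25, 74 and 16 of 231 rotations were as high. With bins merged in pairs the values rose to 0.0717, 0.112, 0.0910 and 0.133. Depth is unknown, so noise in single cells could not be separated from a lack of shared pattern. Pairs of bins are not independent replicates, so no p-value is given.

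Repeated loci supplied most of the strongest far contacts. Among pairs at least 500 kb apart, the top 5 of the 4 maps comprised 6 distinct pairs, and 3 of these were in the top 5 of every map. The pair with rhsC and rhsE (bins 37 and 77) had an observed over expected value of 7.36 in both exponential maps, 8.36 in stationary crosslinked and 17.2 in stationary uncrosslinked cells. The pair with rhsC and rhsB (bins 37 and 182) had 5.10, 4.93, 8.67 and 19.1 in the same order. The bin beside rhsB, with ftsY and zntA (bin 181), reached 6.02, 5.14, 4.52 and 10.9 with rhsC, and rhsC with rhsA (bins 37 and 189) 3.57, 2.92, 5.68 and 12.7. The intD bin of prophage DLP12 and the dcp bin with Qin genes (bins 29 and 82) gave 5.49, 6.74, 4.44 and 11.4. The bin with ykfI and perR and that with yfjJ, in the CP4-6 and CP4-57 prophages (bins 14 and 139), gave 5.28, 2.98, 5.47 and 15.8. Of the 6 pairs, 5 lay within a repeat family, and that of bins 37 and 181 lay in none. The families were drawn up after the top pairs were seen.

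Of the 11 gene lists fixed before the data were examined, the rRNA operons stood apart most. The mean observed over expected value among their bins was 1.43 in the labelled crosslinked exponential map (99.9th percentile of 10000 random lists), 1.30 in the labelled uncrosslinked exponential map (99.8th) and 2.31 in stationary uncrosslinked cells (99.95th). In stationary crosslinked cells 6 of the 7 rRNA bins fell in the lowest 5% of coverage and no pair was left. With no bins left out it gave 1.46 (99.98th percentile). Near-identical rRNA copies cannot be told apart by short reads, so these values are uncertain. The cryptic prophage list gave 1.09 in stationary crosslinked cells (99.2nd percentile) and 1.44 in stationary uncrosslinked cells (99.7th), where the median over pairs was 0.839. In the exponential maps it gave 1.08 (95.4th) and 1.04, inside the central 95% of random lists.

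Of the other lists, 2 lay outside the central 95% in 1 map each. Random lists would put 0.25 to 0.275 lists on each side of that range in each map. Single calls of this kind can therefore arise by chance over the 4 maps. The ribosome and RNA polymerase list reached 1.14 in stationary uncrosslinked cells (98.0th percentile) with a median of 0.969. Only 33 of its 72 pairs lay above 1. Its bin 209, with tufB, also holds rrsB, so the caution on repeated rRNA copies extends to it. The replication control list, with dnaA, dnaN and tus, gave 0.798 over 6 pairs in the labelled crosslinked exponential map (0.7th percentile). The lists of glycerol and energy genes, amino acid biosynthesis, RpoS-dependent genes, nucleoid proteins, H-NS-silenced loci, flagella and insertion sequences lay inside the central 95% in all 4 maps. These calls depended on gene placement, but a move of 1 bin takes each list off its own loci. A signal confined to those loci would be lost by it, so the falls do not tell a fragile call from a localised one. With genes placed 1 bin later or earlier, the rRNA operons gave 0.942 and 1.06 in the labelled crosslinked exponential map, 1.03 and 1.02 in the labelled uncrosslinked one, and 1.05 and 0.957 in stationary uncrosslinked cells. No list stood apart in the labelled uncrosslinked map under either placement. The cryptic prophages fell to 0.971 and 0.901 in stationary uncrosslinked cells, and to 0.952 in stationary crosslinked cells with genes placed earlier. They rose to 2.79 in stationary uncrosslinked and 1.43 in stationary crosslinked cells without the repeat families, but over 5 pairs: without the highest pair (bins 61 and 124, the second with intS) the means were 1.00 and 1.07. Without that pair the main values of 1.44 and 1.09 were 1.19 and 1.05. With bins merged in pairs, the rRNA values of 1.43, 1.30 and 2.31 became 1.11, 1.11 and 1.30.

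**Figure D3:**
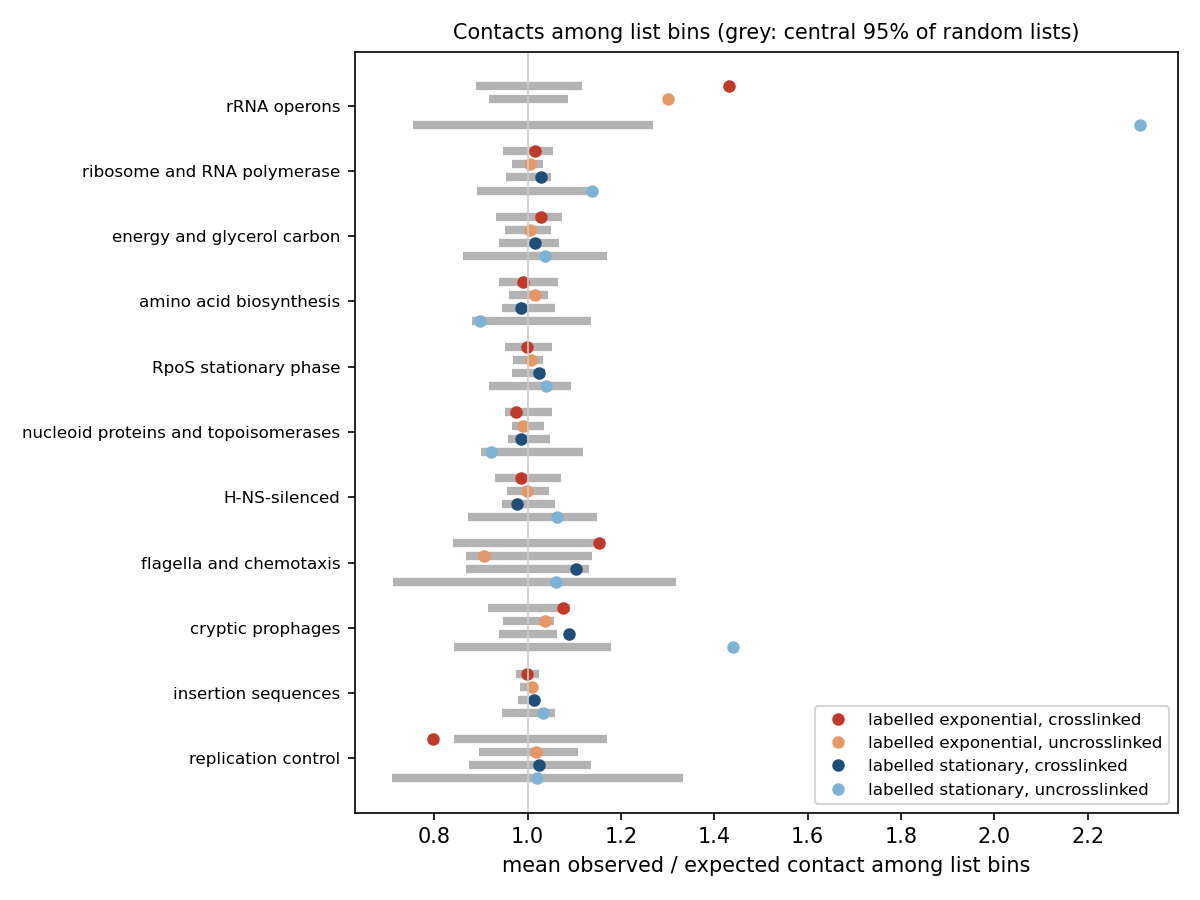
Mean observed over expected contact value among the bins of each gene list (x axis) for the 4 maps (points), with the central 95% of random lists of the same size (grey bars). The rRNA operons lie to the right of the grey bars in the 3 maps where pairs were left, at 1.43, 1.30 and 2.31.

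Far coverage of the lists changed little between maps. The cryptic prophage bins had a median log2 ratio of -0.06 in exponential over stationary phase for the maps labelled crosslinked (9 bins, SD 0.09), at the 0.155th percentile of random lists. In stationary phase their ratio with formaldehyde over without was 0.06 (SD 0.07), at the 98.6th percentile. The stationary crosslinked map enters both ratios, as divisor in the first and dividend in the second, so they are not separate observations. The first was -0.19 with no trend removal and -0.10 with the lowest 10% of bins left out. With all contacts off the diagonal, the first was -0.32, no longer outside the central 95%, and the second turned to -0.13. The second call was also lost with no trend removal, with a running median over 800 kb and with bins merged in pairs. With 10 or 11 lists in each comparison, such calls can also arise by chance. No list lay outside the central 95% in the remaining 2 comparisons. There the cryptic prophages gave 0.04 in exponential over stationary phase for the maps labelled uncrosslinked (8 bins), and -0.02 for formaldehyde in exponential phase as labelled. RpoS-dependent genes, which include dps and katE, gave -0.02 and 0.01 in the growth phase comparisons.

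Macrodomains, large chromosome regions around oriC and the terminus and beside them, showed no detectable enrichment of contacts when pooled. Same-domain pairs exceeded distance-matched pairs in different domains by factors of 1.01, 1.00, 1.00 and 1.02 in the exponential maps labelled crosslinked and uncrosslinked and in the stationary maps with and without formaldehyde. All 4 values lay inside the central 95% of 231 rotations of the borders. The terminus was also taken alone, as a window of 400 kb to either side of dif. It gave 1.04 (98.9th percentile of rotated windows), 0.979 (3.68th), 1.01 (78.6th) and 1.06 (99.8th) in the same order, above the central 95% in 2 maps. In those 2 maps the highest lambdoid prophage pair reached 10.4 and 21.2, above every pair at least 500 kb apart. Such a pair joins the Rac and Qin prophages, whose bins lie inside the window. The window was not recomputed without repeat bins, so an excess of the terminus itself cannot be told from these pairs. The origin window lay inside that range in all 4 maps.

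The deposited tables named for crosslink-independent contacts held cell-by-cell log10 ratios, not a set of called contacts. In the authors' deposited stationary table, the median over pairs at least 100 kb apart was 0.726, a ratio of 5.32, and 0 of 25773 pairs were at or below 0. The lowest belonged to rhsD and rhsE (bins 27 and 77) at 0.00317. The 10 pairs of Rhs bins had a median of 0.222 in this deposited table. In the authors' deposited exponential table the median was 0.296, and 324 of 25868 pairs (1.25%) were at or below 0, the lowest at -0.250 between the dcp bin and bin 168. These values rest on the direction as deposited: turned, 25544 of 25868 pairs would be below 0 and that pair would be the highest. Across pairs, the deposited tables of the growth phases had r = 0.0166 and rho = 0.0184.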

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

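The tests of patterns in this part were all chosen after the result was seen. The ratio of far contacts with formaldehyde to those without differed in direction between growth phases: 0.509 in exponential phase as labelled and 5.14 in stationary phase, with all 232 bins below 1 in one and above 1 in the other. The difference was not tested, since each group has a single pooled map, and 0.509 compares maps whose row totals differ as deposited.

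The exponential maps and the exponential ratio table run in opposite directions. If the table had been made in the stationary order from the maps as named, its correlation with them would be positive, and it was -0.933. That value is the one that showed the pattern and is not a separate test. For exchanged names of the exponential maps, each map was asked to follow the stationary map of the other label, a rule set after the values were seen. Bin-level far coverage, with trend and repeat bins removed, did so in 1 map only. The map labelled crosslinked correlated at 0.704 with stationary uncrosslinked and 0.271 with stationary crosslinked cells (difference 0.433, 95% interval 0.293 to 0.575 over stretches of 209 bins). The map labelled uncrosslinked gave 0.424 with stationary crosslinked and 0.423 with stationary uncrosslinked cells (difference 0.00139, -0.153 to 0.176), so the exchange stays open. Before that rule was set, this test used the sum over both maps, 0.435 (0.264 to 0.628), which came almost wholly from the map labelled crosslinked. Bin-level coverage of the map labelled uncrosslinked had an SD of only 0.03 log2 units, against 0.07 in the other exponential map. With so little spread, its equal correlations cannot exclude an exchange. A test on the distance slopes, run first, did not decide (difference -0.00121 ± 0.0054). An inverted ratio with correct names, which would mean fewer far contacts with formaldehyde, stays open, since low far levels of any origin may give similar profiles.

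The repeated loci stand out in all 4 maps. If ligation that scales with the far level were the cause, the excess over expected at the 26 repeat pairs would be 5.14 times larger with formaldehyde in stationary cells, and it was 1.25 times (95% interval 1.10 to 1.37). None of the 26 joined rRNA operons, which had no pair left in stationary crosslinked cells, whereas the 36 exponential pairs below included them. If unligated reads placed at the wrong copy were the sole cause, the excess would be equal, and the interval's lower end of 1.10 lay above that. The resampling took pairs as independent, although several share a bin such as that of rhsC, and held no spread between samples. The interval may therefore be too narrow to exclude this cause. In the exponential maps, labelled uncrosslinked over labelled crosslinked, the excess ratio was 1.54 (1.19 to 1.92, 36 pairs) against a far-level ratio of 1.97. That interval ended just below 1.97, within its SD over bins of 0.0870, so ligation that scales with the far level was left open there; this margin was set after both values were seen, and the interval alone would have excluded it. A mixture may remain, the stationary test assumes that balanced values of both maps share a scale, and closeness of these loci in the cell was not tested separately.

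The fall of far contacts from oriC to terminus was seen in exponential phase. A factor of each bin acting alike on all its contacts, diagonal included, is removed by balancing to equal row sums. The balanced map labelled crosslinked nevertheless had a ratio of 1.39 (95% interval 1.35 to 1.42). The map labelled uncrosslinked (1.34) does not have equal row sums as deposited, so such a factor stays open there. Fixed properties acting on far contacts alone, such as the number of MluI ends, would give the same ratio in stationary cells, whose upper interval end was at most 1.09. A factor of each bin on its far contacts alone may account for the fall: after balancing, pairs inside a window of 400 kb to either side of oriC had 1.01 times the expected value in the map labelled crosslinked, inside the central 95% of rotated windows in both exponential maps. The terminus window stood at 1.04 (98.9th percentile) in that map, 0.979 (3.68th) in the other exponential map and 1.06 (99.8th) in stationary uncrosslinked cells. Its excess cannot be told from the Rac and Qin prophage pairs inside it, so nothing on the gradient was drawn from it. Gene dosage was not measured, and whether it changes far contacts and those on the diagonal differently was not tested. The ratio of 1.39 therefore gives no verdict on gene dosage.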

How the results depend on the processing

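Gene placement moved by 1 bin, repeat families left out, 10 kb bins and all contacts off the diagonal were alternatives chosen after seeing the data or replacing the written choice; the others were fixed before the data were examined. Of 41 recomputed origin over terminus ratios 39 moved by less than the distance from the middle of their bootstrap interval to its end. All 22 slopes and 12 short-range shares moved by less than their own spreads allowed. Exceptions were 1.29 in the map labelled exponential uncrosslinked with a 400 kb window and 1.03 in stationary crosslinked cells with all contacts off the diagonal. For the other moves below, the cause was not tested.

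The correlations, in the order used in the report, rose to 0.0717, 0.112, 0.0910 and 0.133 with bins merged in pairs and fell to 0.0104, 0.0115, 0.00452 and 0.0130 without repeat families. The exponential crosslinking correlation was 0.324 with distance correction only, which keeps the shared gradient by construction, and the stationary one was 0.0699 with another pseudocount. Macrodomain enrichment in the map labelled exponential uncrosslinked was 1.02 with distance correction only.

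Counts of clustering lists outside the central 95% (2, 1, 1 and 3 in the order exponential labelled crosslinked and uncrosslinked, stationary crosslinked and uncrosslinked) moved as follows. Stationary crosslinked gave 2 with no bins left out. With medians, labelled crosslinked gave 1 and stationary crosslinked 0. Labelled uncrosslinked gave 2 with distance correction only and 2 with merged bins. Without rRNA operons and insertion sequences it gave 0, and stationary uncrosslinked 1. Without repeat families, labelled crosslinked gave 1 and stationary uncrosslinked 1. Placed 1 bin later, the maps gave 1, 0, 3 and 1, and placed earlier 0, 0, 0 and 1. Smaller changes were 4 and 2 in stationary uncrosslinked cells with distance correction only and with medians, and 3 in labelled crosslinked with merged bins. Enrichments turned below 1 in stationary uncrosslinked cells for the ribosome list (0.969 with medians, 0.962 merged, 0.975 later, 0.978 earlier), the cryptic prophages (0.839 with medians, 0.971 later, 0.901 earlier) and the rRNA operons (0.957 earlier). The rRNA operons of the labelled crosslinked map gave 0.942 later, and the cryptic prophages of stationary crosslinked cells 0.952 earlier. Without repeat families the prophage list rose in stationary uncrosslinked (2.79), stationary crosslinked (1.43), labelled crosslinked (1.23) and labelled uncrosslinked cells (1.15). Without rRNA operons and insertion sequences the first 3 of these were 1.995, 1.21 and 1.29. The means rested on 5 and 9 pairs, in which bins 61 and 124 were highest. With distance correction only the prophage list fell to 0.876 in the map labelled crosslinked and 0.918 in that labelled uncrosslinked.

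Counts of lists with changed coverage (1, 0, 0 and 1 in the order growth phase labelled crosslinked, labelled uncrosslinked, formaldehyde in exponential, in stationary phase) became 3, 2, 1 and 0 with no trend removal. The last was 0 with a running median over 800 kb and 0 with merged bins. The first was 2 with no bins left out, 2 with the lowest 10% left out and 0 with all contacts off the diagonal. The third was 1 with the lowest 10% left out and 1 without rRNA operons and insertion sequences. With all contacts off the diagonal the cryptic prophages turned to -0.13 in the last, and 26 bins in the first and 1 in the last passed 1 log2 unit, against 0. A threshold of 0.5 passed 1 bin in the growth phase comparison labelled uncrosslinked. The exponential table's 324 pairs became 162 at a stricter threshold by construction and 0 with merged bins.

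No paired analysis was possible because the deposited maps are pooled, 1 per group, and carry no replicate numbers. For that reason leaving out a replicate, the replicate block and count tests were not run. Inclusion of the diagonal was not run because balancing fixes the row sums, nor were balanced values for the share, which is balanced as deposited. Depth is unknown, so small differences between maps cannot be set against counting error.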

Other observations

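The map labelled exponential crosslinked shared bin-level detail with stationary uncrosslinked cells: the tktA bin, for example, had 1.18 times the map median of far coverage in the first and 1.14 times in the second, against 1.06 in the map labelled exponential uncrosslinked and 0.983 in stationary crosslinked cells. This bin was singled out after its values were seen. The SD of bin-level log2 coverage was 0.07 in that map and 0.08 in stationary uncrosslinked cells, against 0.03 and 0.04 in the map labelled exponential uncrosslinked and in stationary crosslinked cells.

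Of the tests here, that of neighbouring cells was written after similar values had been seen, and that of the arms before. One hypothesis was that loci at like distances from oriC on opposite arms contact each other more than other pairs. No map lay above the central 95% of 116 rotated axes: the map highest by percentile had 1.00055 times the expected value, and the map labelled exponential uncrosslinked, at 0.983, lay just below its range. The criterion written for rejecting the hypothesis required all 4 maps to lie inside, so it was not met as worded. A further hypothesis was that contact patterns extend over neighbouring cells along the diagonal. The highest correlation of diagonal neighbours was 0.00167, inside the range of shuffled cells, whereas cells side by side in a row correlated at 0.0782 to 0.118.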
